A study of Rattus norvegicus with 15 samples.

How the data were processed

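Liver RNA of male Sprague-Dawley rats was measured by RNA sequencing in 15 libraries, 5 in each of 3 groups. The groups were named CON, HFD and ZXD in the sample titles, and the replicate number was taken from the same titles. Total RNA was purified with Trizol and made into libraries with standard Illumina protocols, per the labels. Strand use, the aligner, the read counter, the genome build and the annotation are not given in the sources used here. A simvastatin group that the labels mention was not analysed here.

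The authors deposited 1 table with 21576 genes, holding whole-number read counts and FPKM values for each library, per the file headers. The submitters' processing notes name edgeR, with no role and no version. The deposited FPKM values equalled the deposited count divided by gene length and by the library's total count, with 100% of values above 0 within 0.01%. The deposited FPKM values therefore carry no scaling between libraries beyond the total count, and they were not used for tests. All tests started from the counts. No genome came with the table, so no coordinates are given. Symbols are those of the table. Of these, 16904 were found as symbols and 2002 as synonyms in a RefSeq gene table of the assembly GRCr8, which was used for names alone. Another 2996 genes had provisional symbols, and 142 entries were numbered copies of another symbol. Reads shared between such copies, or within large families such as the Cyp, Ugt2b, Mup and Gbp genes, may have been split or dropped by the counter, so their values are uncertain.

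Total counts lay between 12552449 and 14228052 per library. Counts were scaled with TMM factors of edgeR 4.0.16 in R 4.3.3 and filtered with filterByExpr by group (minimum count 10, minimum total 15), which left 13163 genes for testing and 8413 untested. The kept genes held at least 99.833% of the counts of each library. CPM values use the TMM-scaled library size. Group values are means ± SD of CPM over 5 libraries, and log2 CPM values carry a prior count of 2. A count of 3 corresponded to 0.183 to 0.285 CPM, which covers counting error alone.

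All 15 libraries entered 1 quasi-likelihood fit (robust estimateDisp and glmQLFit) with the group as the sole term and 12 residual degrees of freedom. HFD versus CON, ZXD versus HFD and ZXD versus CON were tested with glmQLFTest. Adjusted p-values are Benjamini-Hochberg values within a comparison. A gene was called at an adjusted p under 0.05, with no fold minimum. Standard errors are the log2 fold change divided by the square root of the F statistic. Genes whose groups do not overlap were counted beside the share that chance gives for 5 against 5 libraries, 0.794%.

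Before the data were examined, 34 gene lists of liver pathways and of markers of other cell types were written, with 707 entries. Of these, 698 were in the table and 655 were tested. Some genes stand in more than 1 list. Lists were tested with camera of limma 3.58.1 on log2 CPM with a preset correlation of 0.01, adjusted over the 34 lists, with an estimated correlation and fry beside it. Each list's calls were counted from the adjusted p over all genes and again adjusted over the list alone. A list score is the mean over members of log2 CPM centred on each gene's mean. Score differences were tested with a two-sided exact permutation test, whose smallest possible p with 5 against 5 libraries is 0.0079.

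The genes named were fixed by a rule before the data were examined. For HFD versus CON and ZXD versus HFD the rule takes a set of genes of sterol, bile acid, fatty acid and thyroid hormone biology whether called or not; some of its genes are not reported here. It adds the 5 called genes with the largest positive and the 5 with the most negative log2 fold change, among those with at least 5 CPM in the higher group, groups that do not overlap and a symbol that is not provisional. It also adds up to 3 called members of each list with the smallest adjusted p. Where fewer than 10 genes are called, it takes the 10 with the smallest p. For ZXD versus CON the fixed genes and the extremes are taken. Genes named outside this rule are said to have been chosen after their values were seen.

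The fit was tested on simulated counts drawn from the real means, library sizes and dispersions. For ZXD versus HFD, over 13163 genes, it recovered 14.9% of the genes changed 1.5-fold, 49.3% of those changed 2-fold and 75.8% of those changed 4-fold, and 5.43% of its calls were false. For HFD versus CON the shares were 14.9%, 47.8% and 84.8%, with 2.46% false calls. For ZXD versus CON they were 13.4%, 52.2% and 89.4%, with 4.51% false calls.

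Comparisons that share libraries were set beside 20 simulations of unchanged groups and 20 splits of the shared group. All 15 libraries were redrawn in the simulations, gene by gene, around fitted group means. ZXD was given the HFD means, or all groups the CON means. The simulations lack the correlation between genes that real livers hold, so their spread may be too narrow. Alternatives planned before the data were examined were RLE factors, no filter, a strict filter (1 CPM in 10 libraries), DESeq2 1.42.0, limma voom, a fit of the compared groups alone, the replicate number as a block, a fold minimum of 1 on the log2 scale, an adjusted p under 0.01 and leaving out each library in turn. Scaling by library totals alone, a length slope as a covariate, removal of the length trend and the macrophage list score as a covariate were added after the data had been seen. The macrophage score differed between the groups, with means of -1.18 in CON, 0.247 in HFD and 0.93 in ZXD. As a covariate it therefore also takes out part of the group difference. A call lost with it does not show that the change comes from immune cells. The length slope is each library's slope of log2 CPM on gene length. It was higher in ZXD (0.013 to 0.087) than in most CON and HFD libraries (-0.079 to 0.034 and -0.094 to 0.037). As a covariate it likewise takes out part of the difference between ZXD and the other groups. Genes were also tested in 100 random splits of the 10 libraries of each comparison.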

Results

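Liver RNA of male Sprague-Dawley rats was sequenced in 3 groups of 5 libraries. CON rats ate normal chow. HFD rats ate a feed made to raise blood lipids, with 2% cholesterol, 8.3% yolk, 7% lard, 16.7% sucrose, 66% base forage, 0.3% sodium cholate, a bile salt that aids cholesterol uptake, and 0.2% propylthiouracil, which blocks thyroid hormone synthesis. ZXD rats ate the same feed and, after its initial 4 weeks, received Zexie Decoction by mouth at 2.2 g per kg per day during the remaining 4 weeks, while HFD rats received saline. Zexie Decoction is a herbal preparation made from the rhizomes of Alisma and Atractylodes. The labels give 10 rats per group but not which rats the libraries came from. If any libraries share an animal, p-values measure only the spread between these samples, which may be technical.

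Libraries held 12972523 to 14228052 counts in CON, 12552449 to 13687385 in HFD and 12688915 to 13532245 in ZXD, with 14720 to 15816 genes above 0. Albumin, the main plasma protein made by hepatocytes, took 8.57% ± 0.628 of the counts in CON (SD, n = 5), 4.33% ± 0.916 in HFD and 3.63% ± 1.23 in ZXD. TMM factors lay between 0.793 and 0.867 in CON and between 1.01 and 1.28 in the other groups. With library totals alone as the scale, the median log2 fold change of all genes moved from 0.02 to 0.44 in HFD versus CON and from 0.03 to 0.46 in ZXD versus CON, so changes against CON are given relative to the TMM scale.

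The HFD against CON comparison asked what the diet changed in liver RNA. The enzymes that make cholesterol fell together in HFD livers. Of 20 tested members, 20 fell, also when adjusted over the list alone, with a median log2 fold change of -1.80 (camera adjusted p = 3.8e-24, adjusted p = 0.00383 with an estimated correlation). Idi1, which isomerises isopentenyl diphosphate, fell by 4.70 on the log2 scale (SE 0.24, edgeR adjusted p = 1.53e-08). Fdps, farnesyl diphosphate synthase, fell from 197 ± 24.7 to 26.0 ± 3.70 CPM (edgeR adjusted p = 7.26e-09), and Cyp51, the lanosterol demethylase, from 448 ± 71.9 to 30.2 ± 6.13 CPM (edgeR adjusted p = 1.53e-08). Squalene epoxidase, Sqle, fell by 2.94 (SE 0.19, edgeR adjusted p = 1.91e-07).

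Among genes of sterol uptake and sensing, most were lower. Of 12 tested members, 8 fell, 2 rose and 2 did not pass, against 8 and 3 adjusted over the list alone (camera adjusted p = 0.0016, adjusted p = 0.0777 with an estimated correlation). With library totals as the scale 6 fell, 3 rose and the median moved from -0.74 to -0.32. Stard4, a cytosolic sterol carrier, fell by 1.87 (SE 0.14, edgeR adjusted p = 1.1e-06).

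Sterol efflux genes moved both ways. Of 9 tested members, 3 rose and 2 fell, against 3 and 3 adjusted over the list alone, with a median of -0.16 (0.26 with library totals as the scale) and a mean of 0.12 (camera adjusted p = 0.971). Abcg1, which exports cholesterol from cells, rose by 2.85 (SE 0.39, edgeR adjusted p = 0.00027), and Mylip, a ubiquitin ligase induced by sterols, by 1.74 (SE 0.31, edgeR adjusted p = 0.00159). Abcg8, a part of the transporter that moves sterols into bile, fell by 2.36 (SE 0.69, edgeR adjusted p = 0.0275). That call was lost without CON 2, CON 3, CON 5, HFD 2 or HFD 5, which leaves 1 lower member in each case (edgeR adjusted p up to 0.0767). The Abcg8 call was also lost by limma voom (adjusted p = 0.0931) and with the replicate number as a block (edgeR adjusted p = 0.0948). With the macrophage score as a covariate its edgeR adjusted p was 0.404. Its partner Abcg5 did not pass at a log2 fold change of -1.59 (SE 0.55, edgeR adjusted p = 0.0509), nor did Abca1, a cholesterol exporter, at -0.33 (SE 0.24, edgeR adjusted p = 0.335), which was 0.10 with library totals as the scale.

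Bile acid genes were mostly not called. In synthesis, 0 of 13 tested members rose and 2 fell, also adjusted over the list alone, with a median of -0.21 that was 0.21 with library totals as the scale (camera adjusted p = 0.231). These were Akr1c14, a hydroxysteroid dehydrogenase, at -1.25 (SE 0.26, edgeR adjusted p = 0.00455), and Slc27a5, the bile acid CoA ligase, at -0.92 (SE 0.26, edgeR adjusted p = 0.0225). The call of Slc27a5 was lost without CON 2, CON 4 or HFD 2, with an edgeR adjusted p of up to 0.0611, and with library totals as the scale (0.114). The calls of Akr1c14, Slc27a5 and Slc10a1 were lost with the macrophage score as a covariate, at log2 fold changes of -0.79, -0.99 and -0.64 (edgeR adjusted p = 0.0719, 0.0765 and 0.0891). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, did not pass at 0.78 (SE 0.47, edgeR adjusted p = 0.245), nor did Cyp8b1, the sterol 12-alpha-hydroxylase, at 0.39 (SE 0.41, edgeR adjusted p = 0.505). In sensing and transport, 1 of 14 tested members rose and 3 fell, also adjusted over the list alone, with a median of -0.33 that was 0.09 with library totals as the scale (camera adjusted p = 0.11), and the higher count was 2 without HFD 1. Abcc3, a basolateral bile salt exporter, rose from 13.8 ± 7.81 to 123 ± 39.5 CPM (edgeR adjusted p = 6.05e-05). Slc10a1, the sodium-dependent bile salt uptake carrier, fell by 1.26 (SE 0.30, edgeR adjusted p = 0.00997), and Nr1h4, the bile acid receptor FXR, fell from 145 ± 34.1 to 61.2 ± 10.6 CPM (edgeR adjusted p = 0.000687). Nr0b2, the repressor SHP, did not pass at -0.22 (SE 0.51, edgeR adjusted p = 0.78), nor did Abcb11, the bile salt export pump, at -0.23 (SE 0.28, edgeR adjusted p = 0.574), and both had positive values, 0.19 and 0.18, with library totals as the scale.

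Most fatty acid and triglyceride synthesis genes were lower. Of 24 tested members, 14 fell and 1 rose, against 15 and 1 adjusted over the list alone (camera adjusted p = 2.61e-09, adjusted p = 0.0141 with an estimated correlation). The higher count was 0 without any of CON 2, CON 3, CON 4, CON 5, HFD 2 and HFD 5, and 2 on library totals. Fasn, fatty acid synthase, fell from 136 ± 39.0 to 17.1 ± 5.90 CPM (edgeR adjusted p = 0.000104), and Elovl6, a fatty acid elongase, from 2.63 ± 0.935 to 0.123 ± 0.0552 CPM, under the level of 3 counts per library (0.183 to 0.285 CPM), so that the size of its fall is uncertain (edgeR adjusted p = 1.68e-05). Acly, which makes cytosolic acetyl-CoA, fell by 2.16 (SE 0.23, edgeR adjusted p = 4.1e-05), and Acss2, an acetyl-CoA synthetase, fell by 2.46 (SE 0.20, edgeR adjusted p = 2.44e-06). Srebf1, the gene of the lipogenic factor SREBP-1, did not pass at -0.04 (SE 0.30, edgeR adjusted p = 0.943), nor did Scd, a desaturase, at -0.41 (SE 0.51, edgeR adjusted p = 0.589), and with library totals as the scale these were 0.39 and 0.0055.

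Lipoprotein genes fell in 14 of 25 tested members and rose in 1, against 15 and 1 adjusted over the list alone (camera adjusted p = 3.95e-07, adjusted p = 0.347 with an estimated correlation). On library totals 9 fell, 1 rose and the median moved from -0.64 to -0.22. Apoa4, an apolipoprotein of triglyceride-rich particles, fell from 1323 ± 395 to 43.3 ± 26.6 CPM (edgeR adjusted p = 5.67e-06), and Apof fell by 2.42 (SE 0.30, edgeR adjusted p = 0.000141). Lpl, the lipase that takes up triglyceride from blood and is low in adult liver, rose from 6.13 ± 2.00 to 251 ± 197 CPM (edgeR adjusted p = 0.000171). Among genes of cholesterol esters and lipid droplets, 3 of 18 tested members rose and 5 fell, against 3 and 6 adjusted over the list alone, with a median of -0.02 (0.40 with library totals as the scale) and a mean of 0.08 (camera adjusted p = 0.554). On library totals 7 rose and 4 fell. Plin3, a droplet coat protein, rose by 1.59 (SE 0.18, edgeR adjusted p = 7.06e-05), and Dgat2, which completes triglyceride synthesis, fell by 1.18 (SE 0.22, edgeR adjusted p = 0.00236). Fatty acid oxidation genes gave 2 higher and 4 lower calls among 35 tested members, against 2 and 2 adjusted over the list alone, with a median of -0.26 that was 0.17 with library totals as the scale, where 5 rose and 1 fell (camera adjusted p = 0.122). The lower calls came to 1 without CON 2, CON 3, CON 5, HFD 2 or HFD 5 and to 2 without HFD 1 or ZXD 5, and the higher calls to 1 without HFD 5. Fabp1, the liver fatty acid carrier, fell from 1007 ± 157 to 254 ± 40.1 CPM (edgeR adjusted p = 1.27e-05), while Cpt1a, the gate of mitochondrial fatty acid uptake, did not pass at -0.30 (SE 0.23, edgeR adjusted p = 0.362), which was 0.11 with library totals as the scale.

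Thyroid hormone responsive genes fell in 5 of 17 tested members and rose in 2, against 9 and 2 adjusted over the list alone and 4 and 4 with library totals as the scale (camera adjusted p = 0.0281, adjusted p = 0.189 with an estimated correlation). Their median moved from -0.88 to -0.45 on library totals. The list was lost with the macrophage score as a covariate (camera adjusted p = 0.0683). Dio1, the deiodinase that thyroid hormone induces, fell from 177 ± 67.8 to 11.5 ± 7.07 CPM (edgeR adjusted p = 0.000134), and Thrsp, a thyroid hormone induced lipogenic gene, fell by 3.93 (SE 0.43, edgeR adjusted p = 5.32e-05). Serpina7, thyroxine-binding globulin, rose by 3.47 (SE 0.39, edgeR adjusted p = 6.6e-05). The thyroid list was written without the direction in which the hormone moves each member, so its rises and falls cannot be sorted by that. Sex-biased liver genes, a list that mixes male-biased and female-biased genes, fell in 11 of 19 tested members and rose in 1, against 11 and 2 adjusted over the list alone (camera adjusted p = 3.61e-05, adjusted p = 0.0954 with an estimated correlation). A fall of this mixed list does not show a change of either bias. The median moved from -1.17 to -0.75 on library totals. Obp3, a male-biased lipocalin, was 226 ± 249 CPM in CON and 0.453 ± 0.272 CPM in HFD (edgeR adjusted p = 8.1e-05), and Srd5a1, a steroid reductase, fell by 2.82 (SE 0.30, edgeR adjusted p = 3.9e-05). Other large falls were those of Car3, a carbonic anhydrase, from 889 ± 475 to 27.8 ± 21.7 CPM (edgeR adjusted p = 0.000382), and of Nat8 and Stac3, at log2 fold changes of -5.18 and -6.83 (edgeR adjusted p = 2.11e-06 and 0.0017). Gimd1 fell from 5.89 ± 3.15 to 0.0964 ± 0.0378 CPM (edgeR adjusted p = 8.72e-05), again under the level of 3 counts. Among called genes of at least 5 CPM in the higher group whose groups do not overlap, the largest rises besides Lpl were those of Fst, the activin-binding protein follistatin, Pla2g7, Neurl3 and Sdr16c6 (edgeR adjusted p = 0.0128, 0.0147, 0.00237 and 0.00437). Fst was 0.0881 ± 0.109 CPM in CON, under the level of 3 counts, and 8.05 ± 8.64 CPM in HFD, and the others rose by 5.82, 5.32 and 5.28 on the log2 scale. In CON, log2 CPM was -2.03 to -0.21 for Pla2g7 and -2.74 (0 counts) to 0.066 for Sdr16c6, so the size of their rises is uncertain too. Limma voom did not call Fst, Pla2g7, Neurl3 or Sdr16c6 (adjusted p = 0.192, 0.379, 0.18 and 0.099), nor Obp3 (0.057). With the macrophage score as a covariate Fst, Pla2g7 and Neurl3 were not called either (edgeR adjusted p = 0.169, 0.339 and 0.0615).

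**Figure D1:**
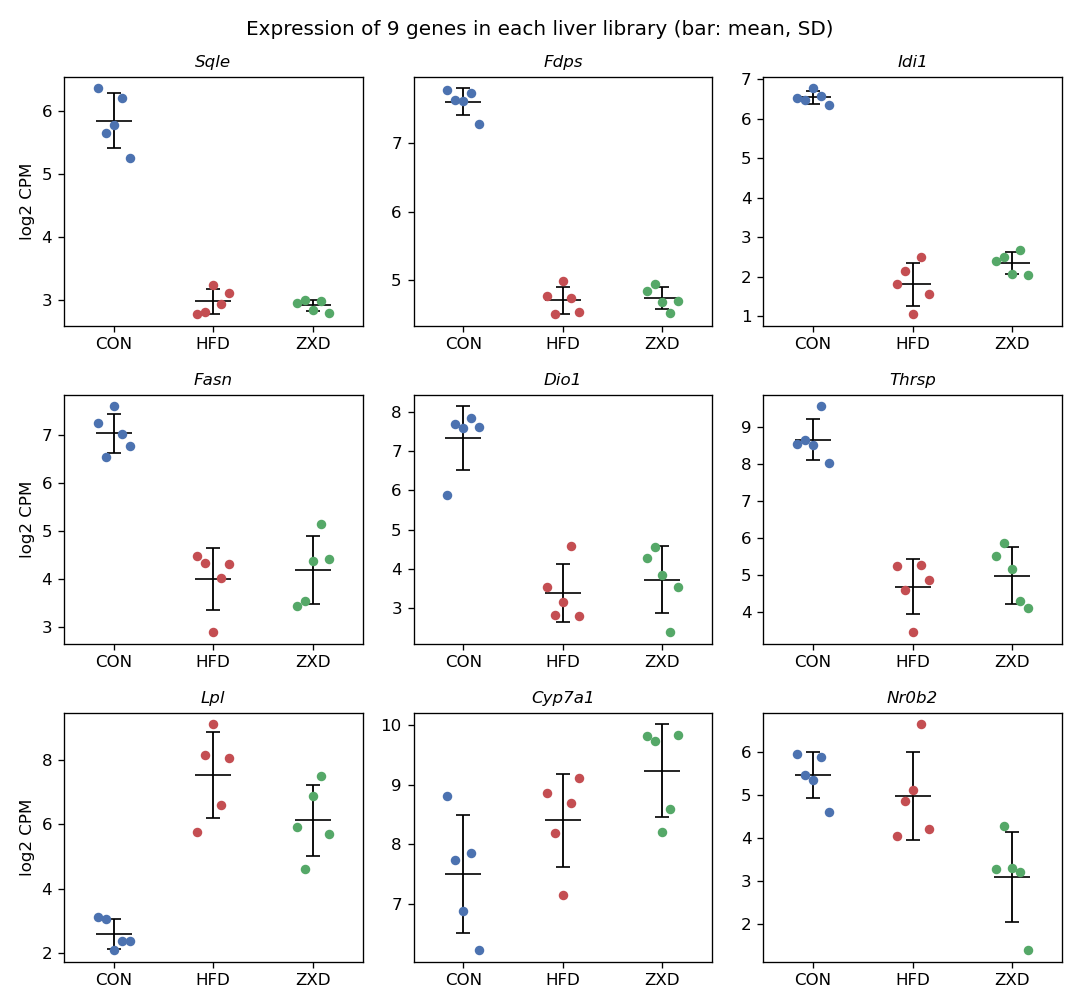
Expression of 9 genes in each liver library as log2 CPM (vertical axis) by group (horizontal axis); points are libraries and bars are the mean and SD of 5. Sqle lies between 5.25 and 6.35 in CON and between 2.77 and 3.24 in HFD, and Lpl between 2.08 and 3.10 in CON and between 5.76 and 9.11 in HFD.

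Markers of immune cells were higher in HFD livers on average, unevenly between libraries. The macrophage score was 1.27 in HFD 2 and 0.84 in HFD 5, 0.013 and 0.014 in HFD 1 and HFD 3, and -0.90 in HFD 4, which lies below CON 1, CON 2 and CON 4 (-0.55, -0.86 and -0.70). T, B and NK cell markers rose in 11 of 18 tested members, against 13 adjusted over the list alone (camera adjusted p = 1.67e-06, adjusted p = 0.347 with an estimated correlation). Their count was 6 without CON 3, CON 4 or HFD 2 and 5 without CON 5 or HFD 5, and 15 on library totals. Cd8a, a cytotoxic T cell marker, was 1.14 ± 0.340 CPM in CON and 12.6 ± 12.6 CPM in HFD (edgeR adjusted p = 0.0131), and Lck, a T cell kinase, rose by 2.12 (SE 0.51, edgeR adjusted p = 0.0101). Macrophage and Kupffer cell markers rose in 13 of 28 tested members and fell in 0, against 17 and 1 adjusted over the list alone (camera adjusted p = 9.74e-05, adjusted p = 0.497 with an estimated correlation). The count was 6 without CON 2, 5 without CON 4, CON 5 or HFD 5, and 4 without CON 3 or HFD 2, and 1 member was called lower without CON 3 or HFD 1. Cd74, the class II invariant chain, rose from 100 ± 23.8 to 1035 ± 812 CPM (edgeR adjusted p = 0.00484), Timd4, a resident Kupffer cell receptor, by 2.5 (SE 0.51, edgeR adjusted p = 0.00423) and Lgals3, galectin-3, by 3.79 (SE 0.91, edgeR adjusted p = 0.0107). With library totals as the scale the macrophage list no longer passed camera (adjusted p = 0.0964), although 20 members were then called higher, nor did it pass fry (adjusted p = 0.0519). Adjusted by its own score it leaves nothing to test. Limma voom did not call Cd8a, Lck, Lgals3 or Timd4 (adjusted p = 0.228, 0.102, 0.128 and 0.0551). None of these, nor Cd74, was called with the macrophage score as a covariate (edgeR adjusted p from 0.0939 to 0.524). Lgals3, Timd4 and Cd74 are members of the list that makes up this score, so for them that adjustment is no test. With the replicate number as a block Cd8a and Lgals3 were not called (edgeR adjusted p = 0.0517 and 0.0522).

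Inflammatory signalling genes rose in 12 of 26 tested members, against 14 adjusted over the list alone (camera adjusted p = 7.39e-05, adjusted p = 0.536 with an estimated correlation). The count was 7 without CON 2 or CON 4, 5 without CON 3 or CON 5, and 4 without HFD 2 or HFD 5. Camera gave an adjusted p of 0.0511 with library totals as the scale, where 18 rose, and 0.955 with the macrophage score as a covariate. Fry gave an adjusted p of 0.0691. Cxcl1, a neutrophil chemokine, rose by 4.57 (SE 1.1, edgeR adjusted p = 0.0106), and Icam1, a leukocyte adhesion molecule, by 1.61 (SE 0.41, edgeR adjusted p = 0.0146). Cxcl1 was not called by limma voom (adjusted p = 0.214), and both were lost with the macrophage score as a covariate (edgeR adjusted p = 0.607 and 0.119). Neutrophil and mast cell markers rose in 3 of 7 tested members, against 4 adjusted over the list alone (camera adjusted p = 0.00625, adjusted p = 0.347 with an estimated correlation). Their count was 1 without CON 2, CON 3, CON 4, CON 5, HFD 2, HFD 3 or HFD 5. Their camera adjusted p was 0.179 with library totals as the scale, where 5 rose, 0.287 with the strict filter and 0.272 with the macrophage score as a covariate. The acute phase list, with 7 higher and 4 lower calls among 25 tested members, against 7 and 5 adjusted over the list alone, did not pass camera (adjusted p = 0.184), and its lower calls came to 2 without CON 2 or CON 4. On library totals 15 rose, 1 fell and the median moved from 0.48 to 0.9. Metallothionein Mt2A rose from 108 ± 65.7 to 703 ± 262 CPM (edgeR adjusted p = 0.000634), and Apcs, serum amyloid P, fell by 1.07 (SE 0.19, edgeR adjusted p = 0.00147). The interferon list, with 6 higher and 2 lower calls among 24 tested members, also adjusted over the list alone, did not pass camera either (adjusted p = 0.23), with 9 higher and 0 lower on library totals. Its higher calls came to 2 without CON 2, CON 3, CON 5 or HFD 2 and to 3 without CON 4 or HFD 5, and its lower calls to 0 without CON 1 and to 1 without CON 2, CON 4, HFD 1, HFD 2 or HFD 5. Irf1, an interferon-induced transcription factor, rose by 2.66 (SE 0.63, edgeR adjusted p = 0.00982, or 0.318 with the macrophage score as a covariate).

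Cholangiocyte markers rose in 6 of 13 tested members and fell in 1, also adjusted over the list alone (camera adjusted p = 0.00543, adjusted p = 0.347 with an estimated correlation). Epcam rose by 1.64 (SE 0.16, edgeR adjusted p = 1.95e-05) and the keratin Krt8 by 1.05 (SE 0.24, edgeR adjusted p = 0.00785), while Onecut1, a transcription factor also of hepatocytes, fell by 4.90 (SE 0.56, edgeR adjusted p = 7.06e-05). With library totals as the scale this list gave a camera adjusted p of 0.156 and 10 higher calls. Hepatocyte markers fell in 6 of 20 tested members and rose in 0, also adjusted over the list alone (camera adjusted p = 9.74e-05, adjusted p = 0.437 with an estimated correlation). That list was lost with the macrophage score as a covariate (camera adjusted p = 0.155, mean -0.22). On library totals 4 fell and the median moved from -0.66 to -0.23. Albumin fell by 1.41 (SE 0.29, edgeR adjusted p = 0.00422) and Ahsg, fetuin-A, by 1.83 (SE 0.26, edgeR adjusted p = 0.000325). Endothelial markers rose in 1 of 18 tested members, also adjusted over the list alone, in 2 without HFD 3 and in 4 on library totals (camera adjusted p = 0.319), and the called gene was Egfl7 at 0.73 (SE 0.18, edgeR adjusted p = 0.0102). The calls of Krt8, albumin and Egfl7 were lost with the macrophage score as a covariate, at log2 fold changes of 0.89, -1.06 and 0.42 (edgeR adjusted p = 0.089, 0.0542 and 0.198). Stellate cell and matrix genes fell in 2 of 26 tested members, also adjusted over the list alone (camera adjusted p = 0.958). They gave 1 lower call without CON 3 or HFD 5, 1 higher call without CON 2 or HFD 1, and 2 higher calls without HFD 4, ZXD 2 or ZXD 4. On library totals 7 of these genes rose, 1 fell and the median moved from 0.24 to 0.66. Fn1, fibronectin, fell by 1.16 (SE 0.23, edgeR adjusted p = 0.0039). Among the markers of tissues beside the liver, 2 of 4 adipocyte, 1 of 2 exocrine pancreas and 0 of 4 red cell markers rose, and 1 red cell marker fell, all also adjusted over the list alone, with camera adjusted p = 0.14, 0.399 and 0.778. The red cell median was -0.39, or 0.05 with library totals as the scale. These counts came to 3 adipocyte and 0 lower red cell markers on library totals, to 1 adipocyte marker without HFD 2, to 0 pancreas markers without CON 3, CON 4, CON 5, HFD 1, HFD 2, HFD 3, HFD 5, ZXD 3 or ZXD 5, and to 0 lower red cell markers without CON 1, CON 2, CON 3, CON 5, HFD 2, HFD 3, HFD 4 or HFD 5.

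Several metabolic lists were lower on the TMM scale, and 3 of them were not called with the macrophage score as a covariate. With that score as a covariate circadian clock (mean -0.12, camera adjusted p = 0.157), glucose metabolism (-0.19, camera adjusted p = 0.092) and amino acid metabolism (0.15, camera adjusted p = 0.685) lost their calls, the last with its sign changed. Circadian clock genes fell in 9 of 18 tested members and rose in 2, also adjusted over the list alone (camera adjusted p = 0.00933, adjusted p = 0.347 with an estimated correlation), with Cry1, a clock repressor, at -1.85 (SE 0.24, edgeR adjusted p = 0.000194) and Npas2, a clock activator, at 3.74 (SE 0.76, edgeR adjusted p = 0.00401, limma voom adjusted p = 0.105). On library totals 4 clock genes rose and 5 fell, with a median of -0.21. Glucose metabolism genes fell in 9 of 25 tested members and rose in 2, against 13 and 4 adjusted over the list alone (camera adjusted p = 0.00284, adjusted p = 0.347 with an estimated correlation), and 1 rose without CON 3 or CON 5. On library totals 4 rose, 6 fell and the median moved from -0.63 to -0.21. Pklr, liver pyruvate kinase, fell by 1.56 (SE 0.29, edgeR adjusted p = 0.00231) and Khk, ketohexokinase, by 1.27 (SE 0.24, edgeR adjusted p = 0.00238). Amino acid and urea cycle genes fell in 6 of 24 tested members, also adjusted over the list alone (camera adjusted p = 0.00695, adjusted p = 0.747 with an estimated correlation), and in 2 without CON 2, CON 3, HFD 2 or HFD 5 and 3 without CON 4, CON 5 or HFD 3. On library totals 2 of these rose, 2 fell and the median was -0.05, and fry gave an adjusted p of 0.222. Oxidative phosphorylation genes fell in 16 of 34 tested members, against 22 adjusted over the list alone (camera adjusted p = 1.94e-07, adjusted p = 0.347 with an estimated correlation), but with library totals as the scale 3 rose, 0 fell and the median turned from -0.40 to 0.02. Without CON 2, CON 3 or CON 5 the count was 8, without CON 4 it was 9 and without HFD 5 it was 7. Endoplasmic reticulum stress genes fell in 6 of 20 tested members and rose in 1, also adjusted over the list alone (camera adjusted p = 0.0271, adjusted p = 0.467 with an estimated correlation), but 3 rose and 2 fell with library totals as the scale, where the median turned from -0.42 to 0.01. Their camera adjusted p was 0.0734 without CON 3, 0.0524 without HFD 1, where 2 rose, and 0.0759 without HFD 4. Xbp1, a factor of that response, fell by 1.02 (SE 0.21, edgeR adjusted p = 0.004), and Asns, asparagine synthetase, rose by 3.35 (SE 0.51, edgeR adjusted p = 0.000641).

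Xenobiotic metabolism genes moved both ways, with 5 higher and 10 lower calls among 45 tested members, against 6 and 10 adjusted over the list alone (camera adjusted p = 0.23). With library totals as the scale 14 rose and 5 fell, and the median turned from -0.24 to 0.17. The lower calls came to 6 without CON 2, CON 4, CON 5, HFD 2 or HFD 5 and to 5 without CON 3, and the higher calls to 3 without CON 3, CON 4 or CON 5. Abcb1b, a drug efflux pump, rose from 19.7 ± 11 to 515 ± 297 CPM (edgeR adjusted p = 4.1e-05), and Cyp2b3 fell by 1.67 (SE 0.22, edgeR adjusted p = 0.000187). Oxidative stress genes rose in 6 of 22 tested members and fell in 3, against 8 and 3 adjusted over the list alone (camera adjusted p = 0.615), and 3 rose without CON 5 or HFD 2. On library totals 9 rose and 2 fell, with a median of 0.50 against 0.09. Nfe2l2, which encodes NRF2, rose by 0.62 (SE 0.11, edgeR adjusted p = 0.00143), and Gclm, a glutathione synthesis gene, fell by 1.03 (SE 0.17, edgeR adjusted p = 0.00103). Immediate early and heat shock genes rose in 1 of 19 tested members and fell in 5, against 2 and 6 adjusted over the list alone, with a median of -0.16 that was 0.26 with library totals as the scale, where 3 rose and 3 fell (camera adjusted p = 0.319). Cell cycle genes rose in 1 of 24 tested members, or 0 adjusted over the list alone (camera adjusted p = 0.122), and in 4 on library totals, where the median moved from 0.70 to 1.12. Without single libraries the immediate early calls lay between 0 and 2 higher and between 2 and 6 lower, and the cell cycle calls between 0 and 2. Cytosolic ribosomal genes fell in 1 of 33 tested members, also adjusted over the list alone (camera adjusted p = 0.132), and rose in 27 with library totals as the scale, where their median moved from 0.13 to 0.55.

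In all, edgeR called 2758 of 13163 genes between HFD and CON, 1322 higher and 1436 lower. Of these, 764 rose and 485 fell by at least 2-fold, and 1980 genes (15%) had groups that did not overlap, where chance gives 0.794%. With library totals as the scale 91.4% of 5895 calls were higher, against 47.9% of the calls on the TMM scale. The count fell to 1734 without CON 3, 1822 without CON 4, 1697 without HFD 2 and 1730 without HFD 5. Of the 17 lists that camera passed, fry passed 14, all but the inflammatory, macrophage and amino acid lists. They include T, B and NK cell markers (fry adjusted p = 0.00951), lipoproteins (0.00163) and oxidative phosphorylation (0.00581). The exact permutation test of these scores gave an adjusted p of 0.0208 for each. It gave 0.108 for cholangiocyte markers and 0.415 for endoplasmic reticulum stress, which fry also passed.

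**Figure D2:**
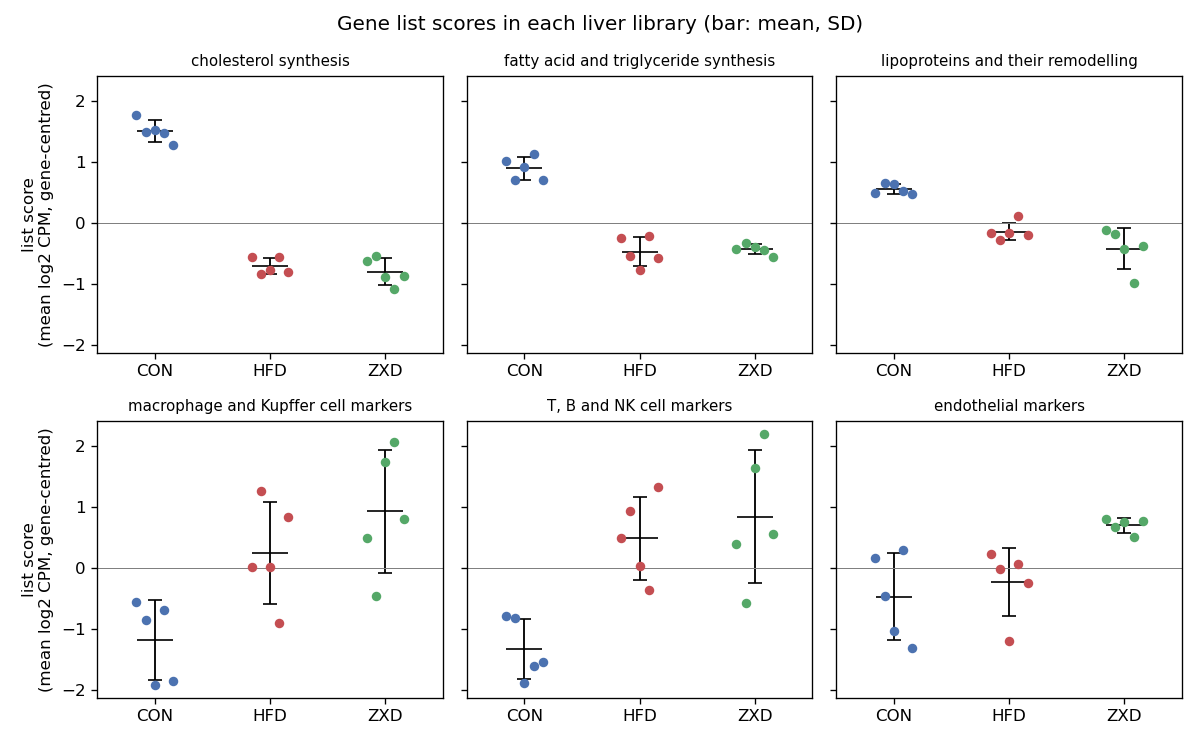
Scores of 6 gene lists in each liver library (vertical axis, mean log2 CPM of the members centred on each gene's mean) by group (horizontal axis); points are libraries and bars are the mean and SD of 5. Cholesterol synthesis scores lie between 1.28 and 1.77 in CON and between -1.09 and -0.54 in HFD and ZXD, and endothelial scores between 0.51 and 0.81 in ZXD and between -1.31 and 0.29 in CON and HFD.

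The ZXD against HFD comparison asked whether the decoction changed liver RNA in rats on the diet, as the series title frames it. Sqle, which fell in HFD livers, was 7.76 ± 1.12 CPM in HFD and 7.37 ± 0.477 CPM in ZXD (SD, n = 5), a log2 fold change of -0.07 (SE 0.18, edgeR adjusted p = 0.857). Fasn was 17.1 ± 5.90 and 20 ± 9.97 CPM (log2 fold change 0.23, SE 0.34, edgeR adjusted p = 0.747). None of the genes fixed in advance passed the test.

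No gene was called by edgeR, and the smallest adjusted p was 0.11. At an unadjusted p under 0.05 there were 2167 genes, 1295 higher and 872 lower, where 658 are expected by chance and simulations of unchanged ZXD groups gave 611.8 on average. Neither figure reflects how widely such a count varies when genes are correlated. Of 100 random splits of these libraries, 10 gave as many, the real one among them (highest other 4350). Limma voom called 0 genes and DESeq2 348, of which 216 were higher and 132 lower. Groups did not overlap in 484 genes (3.68%), where chance gives 0.794%. Without HFD 1 edgeR called 7 genes, Dlat, Dlc1_1, Gda, Itgb3, Mbnl1, Prelp and Rprm. Without HFD 3 it called 1, Mmp15, at a log2 fold change of -1.32 (SE 0.17, edgeR adjusted p = 0.0188). These genes, except Prelp, were chosen after their values were seen.

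Among the fixed genes, the one with the smallest p was Nr0b2, the repressor SHP, at 39.7 ± 34.6 CPM in HFD and 10.0 ± 6.05 CPM in ZXD, a log2 fold change of -1.99 (SE 0.53, edgeR adjusted p = 0.155). Cyp7a1, which SHP represses, was 373 ± 161 and 667 ± 301 CPM (0.84, SE 0.47, edgeR adjusted p = 0.382), and Cyp8b1 620.0 ± 149 and 797 ± 290 CPM (0.36, SE 0.41, edgeR adjusted p = 0.66). Abca1 had groups that did not overlap, at 108 ± 26.0 and 163 ± 18.6 CPM (0.59, SE 0.24, edgeR adjusted p = 0.243). Log2 fold changes of the others were -0.41 for Abcb11, -0.41 for Abcg5, -1.19 for Abcg8, -0.59 for Srebf1, -0.80 for Scd, -0.04 for Cpt1a, 0.35 for Dio1 and 0.32 for Thrsp, with edgeR adjusted p between 0.339 and 0.939. The 10 genes with the smallest p were Ubash3b, Ssh2, Prelp, Asap1, Akap13, Rapgef2, Alms1 and Wdr7, at positive log2 fold changes from 0.61 to 2.00, and LOC103693914 and Ankrd54, at -1.91 and -0.66. Their edgeR adjusted p lay between 0.11 and 0.139, so none was called. Ubash3b, a phosphatase that tempers receptor signalling, was 2.05 ± 0.742 CPM in HFD and 8.23 ± 0.966 CPM in ZXD, and Prelp, a matrix protein, 5.70 ± 1.22 and 11.7 ± 2.29 CPM.

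Camera with its preset correlation passed 8 lists, while no single gene passed the test. That count is no evidence of a shift, since 64 of 100 random splits of these 10 libraries passed as many. The other splits passed a median of 10 lists. Endothelial markers, of which 18 of 18 tested members had a positive value, were higher in ZXD livers with a median of 0.92 (camera adjusted p = 2.54e-07, adjusted p = 0.991 with an estimated correlation). Over all genes 0 of them were called, and 10 were called higher adjusted over the list alone. Their scores averaged 0.70 ± 0.12 in ZXD and -0.23 ± 0.56 in HFD, a difference with an exact permutation p of 0.00794 (the smallest this design gives) and 0.27 after adjustment over the lists. With each library's slope of log2 CPM on gene length as a covariate, the list no longer passed camera (adjusted p = 0.0595). That slope was 0.013 to 0.087 in ZXD and -0.094 to 0.037 in HFD, so as a covariate it also takes out part of the group difference. Cholangiocyte markers were lower with a median of -0.58 (camera adjusted p = 0.000799, adjusted p = 0.991 with an estimated correlation), with 0 calls over all genes and 5 lower adjusted over the list alone, and camera gave 0.0552 with the length slope as a covariate.

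Cell cycle genes (median 1.15, camera adjusted p = 0.00155), macrophage and Kupffer cell markers (median 0.63, camera adjusted p = 0.00441) and stellate cell and matrix genes (median 0.40, camera adjusted p = 0.0375) were higher, and genes of xenobiotic metabolism (median -0.25, camera adjusted p = 0.000607), lipoproteins (median -0.22, camera adjusted p = 0.00977) and cytosolic ribosomal proteins (median -0.20, camera adjusted p = 6.28e-05) were lower. Each had an adjusted p = 0.991 with an estimated correlation, and 0 calls over all genes. Cell cycle scores were -0.61 and -0.50 in ZXD 1 and ZXD 2, within the HFD range of -0.74 to 0.51, and 1.13, 2.08 and 1.32 in ZXD 3, ZXD 4 and ZXD 5. Adjusted over the list alone, 3 stellate and matrix genes were called higher and 0 genes in the others. Without ZXD 4 camera gave an adjusted p of 0.167 for cell cycle, 0.137 for macrophage markers, 0.437 for stellate genes, 0.17 for xenobiotic metabolism and 0.437 for lipoproteins. Adjusted for the macrophage score, camera gave an adjusted p of 0.376 for cell cycle, 0.359 for xenobiotic metabolism and for lipoproteins, and 0.817 for stellate genes, whose mean changed sign (-0.0049). With the length trend removed it gave 0.119 for lipoproteins and 0.0589 for stellate genes. The length slope as a covariate gave 0.121 for xenobiotic metabolism, and the strict filter 0.0501 for cell cycle (camera adjusted p). No list passed fry with a set direction (adjusted p from 0.279 to 0.646 for the 8 lists). In the mixed fry test, which takes rises and falls together, sterol uptake and sensing passed (adjusted p = 0.0156). That list did not pass camera (adjusted p = 0.242) and had 2 members higher adjusted over the list alone. Its score had an exact permutation p of 0.0397, or 0.45 after adjustment over the lists. Without HFD 4 camera gave 0.199 for macrophage markers, 0.18 for stellate genes and 0.0806 for lipoproteins. The stellate list was also lost without CON 1 (camera adjusted p = 0.0595), CON 5 (0.0517), HFD 1 (0.159), HFD 3 (0.649) or ZXD 5 (0.0569). The ribosomal list was lost with the length trend removed (camera adjusted p = 0.433) and turned to higher with the length slope as a covariate (camera adjusted p = 0.0115). The other 26 lists did not pass camera, among them cholesterol synthesis (median -0.07, camera adjusted p = 0.343), bile acid synthesis (0.04, camera adjusted p = 0.898), fatty acid and triglyceride synthesis (-0.04, camera adjusted p = 0.971) and thyroid hormone responsive genes (0.32, camera adjusted p = 0.343).

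The ZXD against CON comparison showed how treated livers differed from those of rats on normal chow. Cholesterol synthesis genes fell in 20 of 20 tested members, also adjusted over the list alone, with a median of -1.95 (camera adjusted p = 1.55e-22, adjusted p = 0.00521 with an estimated correlation). Sqle fell by 3.01 (SE 0.19, edgeR adjusted p = 1.7e-07) and Fasn by 2.76 (SE 0.36, edgeR adjusted p = 0.000157). Dio1 and Thrsp fell by 3.59 and 3.61 (SE 0.48 and 0.43, edgeR adjusted p = 0.000209 and 8.72e-05).

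Cyp7a1 rose from 217 ± 145 CPM in CON to 667 ± 301 CPM in ZXD (SD, n = 5, edgeR adjusted p = 0.02), a call that was lost without CON 3 (edgeR adjusted p = 0.0569). It was also lost with the length slope, which differed between the groups, as a covariate (log2 fold change 0.96, edgeR adjusted p = 0.212). With the macrophage score as a covariate the log2 fold change was 1.62 and the call was lost (edgeR adjusted p = 0.202). Nr0b2 fell by 2.21 (SE 0.54, edgeR adjusted p = 0.00752), and the sterol transporter genes Abcg5 and Abcg8 by 2.00 and 3.55 (SE 0.56 and 0.74, edgeR adjusted p = 0.0145 and 0.00372). With the macrophage score as a covariate Nr0b2, Abcg5 and Abcg8 were not called (edgeR adjusted p = 0.29, 0.881 and 0.424). Abcg5 was also not called with the length slope as a covariate (edgeR adjusted p = 0.0814) or with the replicate number as a block (0.051). Abca1, Abcb11, Cpt1a, Cyp8b1, Scd and Srebf1 did not pass, at 0.26, -0.63, -0.34, 0.76, -1.20 and -0.63 (edgeR adjusted p = 0.422, 0.0919, 0.275, 0.17, 0.0866 and 0.124), and Cpt1a was 0.07 with library totals as the scale. Among the extremes of called genes of at least 5 CPM whose groups do not overlap, Ubd, a ubiquitin-like protein of immune responses, rose by 5.91 (SE 1.13, edgeR adjusted p = 0.00235) and Pla2g7 by 6.52 (edgeR adjusted p = 0.00587). The log2 CPM of Pla2g7 was -2.03 to -0.21 in CON, so the size of its rise is uncertain. Mmp9, a matrix metalloprotease of neutrophils and macrophages, Ankdd1a and Fst rose from levels in CON of about 3 counts per library or fewer, which leaves the size of the rise uncertain. They were 0.253 ± 0.177, 0.0708 ± 0.0748 and 0.0881 ± 0.109 CPM in CON, and 25.7 ± 30.9, 5.98 ± 7.45 and 5.03 ± 6.86 CPM in ZXD (edgeR adjusted p = 0.00206, 0.00431 and 0.0145). Limma voom did not call Mmp9, Pla2g7, Ankdd1a or Fst (adjusted p = 0.159, 0.248, 0.076 and 0.234), nor Obp3 (0.067). With the macrophage score as a covariate Ubd, Mmp9, Pla2g7, Ankdd1a and Fst were not called (edgeR adjusted p = 0.372, 0.395, 0.841, 0.817 and 0.863). Stac3 and Car3 fell, at -6.75 and -5.65 (edgeR adjusted p = 0.00154 and 0.000168). Obp3, Gimd1 and the pseudogene Cyp3a85-ps fell to about 3 counts per library or fewer, at 0.18 ± 0.135, 0.0488 ± 0.109 and 0.219 ± 0.209 CPM, from 226 ± 249, 5.89 ± 3.15 and 8.90 ± 4.77 CPM (edgeR adjusted p = 5.14e-05, 5.14e-05 and 0.00104).

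Markers of immune and endothelial cells were higher on average in ZXD than in CON livers. The hepatocyte score differed by -0.624 (exact permutation p = 0.0317, or 0.0567 after adjustment over the lists). In ZXD 4 albumin took 1.76% of the counts, and Tf instead of albumin was the top gene. The inflammatory score of ZXD 2 (-0.84) lay below those of CON 1 and CON 2 (-0.74 and -0.80), and the cell cycle scores of ZXD 1 and ZXD 2 (-0.61 and -0.50) within the CON range of -1.06 to -0.21, against 1.13, 2.08 and 1.32 in ZXD 3, ZXD 4 and ZXD 5. With the macrophage score as a covariate camera no longer passed T, B and NK cell markers, inflammatory signalling or cell cycle genes (adjusted p = 0.277, 0.369 and 0.278), and the means of the last 2 changed sign (-0.19 and -0.36). Macrophage and Kupffer cell markers rose in 23 of 28 tested members, against 24 adjusted over the list alone (camera adjusted p = 1.18e-07, adjusted p = 0.436 with an estimated correlation), and in 15 without ZXD 4. T, B and NK cell markers rose in 16 of 18, against 17 adjusted over the list alone (camera adjusted p = 2.78e-07, adjusted p = 0.436 with an estimated correlation), and inflammatory signalling genes in 22 of 26, against 23 higher and 1 lower adjusted over the list alone (camera adjusted p = 2.7e-06, adjusted p = 0.48 with an estimated correlation), with 1 lower call without CON 1 or CON 4. Endothelial markers rose in 10 of 18, against 14 adjusted over the list alone (camera adjusted p = 2.49e-05, adjusted p = 0.438 with an estimated correlation), and in 4 without CON 2, 5 without CON 3 and 6 without CON 5, but in 18 on library totals. Cell cycle genes rose in 13 of 24, against 16 adjusted over the list alone (camera adjusted p = 0.000467, adjusted p = 0.526 with an estimated correlation), in 7 without CON 3 and in 6 without CON 5 or ZXD 4, and camera gave 0.0708 with library totals as the scale, where 18 rose. Lipoprotein genes fell in 17 of 25 and rose in 1, against 19 and 1 adjusted over the list alone (camera adjusted p = 1.58e-09, adjusted p = 0.235 with an estimated correlation). On library totals 13 fell, 2 rose and the median moved from -0.92 to -0.52. Of the 34 lists, 18 passed camera and 2 of them, cholesterol synthesis and fatty acid and triglyceride synthesis, passed with an estimated correlation (adjusted p = 0.00521 and 0.0161).

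In all, edgeR called 4299 genes between ZXD and CON, 2356 higher and 1943 lower, with 1612 higher and 572 lower by at least 2-fold. Groups did not overlap in 2367 genes (18%), where chance gives 0.794%. With library totals as the scale 90.6% of 6674 calls were higher, against 54.8% on the TMM scale.

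The comparisons against CON share the CON libraries. They had 2055 called genes in common, 2055 of them with the same sign, 977 higher and 1078 lower, where independent lists would share 236.6 and 212. Another 703 genes were called in HFD alone and 2244 in ZXD alone, which does not show that they differ between HFD and ZXD, where edgeR called 0 genes (2167 at an unadjusted p under 0.05, 348 by DESeq2 and 0 by limma voom). Simulations with all groups redrawn around the CON means gave 0 genes in common. No group differed there, so that 0 does not show how much the shared libraries add to the overlap. The covariance of the fold changes was 0.64, against 0.06 in those simulations, a difference of 0.58. Over 20 splits of the CON libraries between the comparisons it averaged 0.59, with 416 to 761 genes called in both, of which at least 94.5% had the same sign.

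**Figure D3:**
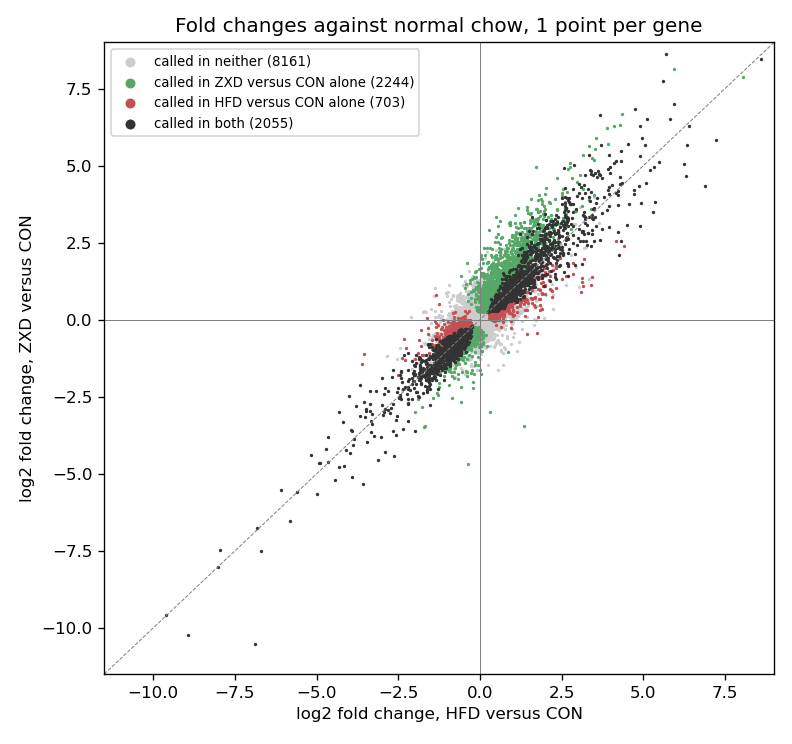
Log2 fold change of each gene in HFD versus CON (horizontal axis) and in ZXD versus CON (vertical axis); each point is 1 gene, coloured by whether edgeR called it in both comparisons (2055), in ZXD versus CON alone (2244), in HFD versus CON alone (703) or in neither, and the dashed line marks equal values. The 2055 genes called in both lie in the quadrants of equal sign.

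The question whether ZXD moved genes back toward CON rests on HFD versus CON and ZXD versus HFD, which share the HFD libraries with opposite signs. Genes called in both with opposite signs numbered 0 by edgeR and 88 by DESeq2, with 2167 genes at an unadjusted p under 0.05 in ZXD versus HFD. Without HFD 1 edgeR gave 5, Dlat, Gda, Itgb3, Prelp and Rprm, of which all but Prelp were chosen after their values were seen. Of the 2758 genes called between HFD and CON, 57.8% had the opposite sign in ZXD versus HFD. Simulations with HFD and ZXD redrawn around the same means gave 63.1% on average. The covariance over all 13163 genes was -0.0078 (correlation -0.02 across genes, which are not independent replicates), against -0.06 in the simulations, a difference of 0.06. With the HFD libraries divided between the comparisons in 20 ways it averaged 0.06 and ranged from -0.07 to 0.26.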

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

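Dixon's rule, which sets apart a library far from the others of its group, does so in about 1 in 20 groups of 5 by chance. Of 489 groups tested, 20 held a value it set apart, where 24.4 are expected, so the values below are no more frequent than chance, and none was left out of any test. The slope of log2 CPM on gene length was 0.0134 in ZXD 3 (0.067 to 0.0873 in the other ZXD libraries). The lipoprotein score was 0.108 in HFD 4 (-0.275 to -0.164 in the others), and the glucose metabolism score -0.569 in ZXD 4 (-0.0458 to 0.144).

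In CON, log2 CPM was 5.89 for Dio1 in CON 1 (7.60 to 7.86 in the other CON libraries), 4.64 for Nat8 in CON 1 (5.50 to 5.55), 9.52 for Glud1 in CON 1 (10.1 to 10.3) and 5.09 for Rapgef2 in CON 1 (4.54 to 4.69). It was 8.35 for Cyp51 in CON 5 (8.83 to 9.01), 3.21 for Irf1 in CON 5 (3.92 to 4.03), 7.25 for Akap13 in CON 5 (6.85 to 6.96) and 7.37 for Apof in CON 4 (8.08 to 8.31). S100a8 was -2.06 in CON 1 and -2.74, the value of 0 counts, in the others.

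In HFD, log2 CPM was 7.00 for Nr1h3 in HFD 1 (6.80 to 6.85 in the other HFD libraries), 5.43 for Dusp1 in HFD 1 (7.74 to 8.05), 11 for Ahsg in HFD 3 (11.8 to 12.2), 7.91 for Apcs in HFD 5 (8.36 to 8.44) and 1.26 for Cd79b in HFD 5 (-0.0559 to 0.165). In ZXD it was 6.75 for Srebf1 in ZXD 2 (6.22 to 6.33 in the other ZXD libraries), 5.96 for Cideb in ZXD 4 (6.63 to 6.86) and -1.34 for Gimd1 in ZXD 4 (-2.74, 0 counts, in the others).

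The tests in the following paragraphs, on technical explanations and on other splits of the libraries, were chosen after the results were seen. Endothelial markers stood higher in ZXD than in HFD, by 0.869 on the log2 scale against other genes. A trend on gene length is argued against, since the difference was 0.834 with the trend removed (camera adjusted p = 1.21e-07). The cholangiocyte score differed by -0.683, which lies 1.62 below the endothelial difference (SE 0.423, exact p = 0.0159). This argues against a lower share of hepatocyte RNA only in part, since that list also holds genes of hepatocytes such as Onecut1. The hepatocyte score itself differed by 0.05 (SD 0.619 in ZXD and 0.239 in HFD, exact p = 0.921). An axis between libraries that also runs through CON and HFD stays open: with the length slope as a covariate the difference was 0.199 (camera adjusted p = 0.0595). The slope was higher in ZXD than in HFD on average, so as a covariate it also takes out part of the group difference. Over the 10 CON and HFD libraries the endothelial score and the slope, each centred within its group, had r = 0.683 (permutation p = 0.0417), r = 0.666 without the 2 farthest libraries, and a Spearman rho of 0.552 (permutation p = 0.102). The decoction, which the groups differ in, stays open as well, as untested.

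Macrophage and Kupffer cell markers stood higher in HFD than in CON, by 1.34 on the log2 scale against other genes. A single library rich in immune cells is argued against, since the difference was 1.1 without HFD 2, where it was lowest. This test was put in place of a count of called members, which was 4 without HFD 2 and would have spoken for that explanation, because the count was 4 without CON 3 too. Blood left in the liver is argued against by a red cell score difference of 0.0598 (SE 0.384, exact p = 0.897), from 4 markers, and a lower share of hepatocyte RNA, as the whole cause, by an endothelial score difference of 0.235, which lies 1.19 below the macrophage difference (SE 0.466, exact p = 0.0556). Such a share stays open as a part of the cause, since the cholangiocyte score was 0.778 higher and the hepatocyte score differed by -0.674, and the diet, which the groups differ in, remains a hypothesis, found and tested on the same libraries.

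Of the genes called between HFD and CON, 57.8% had the opposite sign in ZXD versus HFD. Simulations with HFD and ZXD redrawn around the same means gave 63.1% on average and at most 64.4%. A shared HFD group alone can thus give such a share. The genes were redrawn independently there, so that range may be too narrow to judge by. With the real HFD libraries divided between the comparisons in 20 ways, the covariance of the fold changes ranged from -0.07 to 0.26. The share of opposite signs therefore does not show a return toward CON in ZXD, and it does not exclude one, also not for single genes.

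Other splits of the 10 libraries of each comparison show how often such counts arise by chance. For HFD versus CON, 1 of 100 splits, the real one, gave as many calls as 2758 (highest other 36). At an unadjusted p under 0.05, 1 gave as many genes as 4867 (highest other 3367). As many lists passing camera as 17 came from 17 splits (median of the others 10, highest other 23). For ZXD versus CON, 1 of 100 gave 4299 calls (highest other 1035) and 1 gave 5752 genes at an unadjusted p under 0.05 (highest other 4053). As many lists as 18 came from 28 splits (median of the others 15, highest other 23). Chance is thus unlikely for these counts of genes, though 1 of 100 is the smallest share such a test can give. For the counts of lists chance stays open. The splits also treat the libraries as independent of each other.

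For ZXD versus HFD chance is not excluded. Of 100 splits, 10 gave as many at an unadjusted p under 0.05 as 2167 (highest other 4350) and 11 gave as many DESeq2 calls as 348 (highest other 3012). As many lists as 8 came from 64 splits (median of the others 10, highest other 24). For opposite signs, 6 gave as many by DESeq2 as 88 (highest other 1225). By edgeR the real counts of calls and of opposite signs were 0, which 100 of 100 splits reach by necessity (highest other 2240 and 471), so these counts test nothing. The split with 2240 calls set HFD 1, HFD 3, HFD 4, ZXD 1 and ZXD 2 against the rest, which points to a structure of the samples other than the groups. These are the 5 of the 10 libraries with the lowest macrophage scores (0.013, 0.014, -0.90, 0.50 and -0.46, against 0.80 to 2.07 in the rest).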

How the results depend on the processing

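Other settings changed the counts of called genes as follows. HFD versus CON gave 2758 calls, and 5895 with library totals alone as the scale, 974 with the macrophage score as a covariate, 1249 with the fold minimum and 993 at an adjusted p under 0.01. Leaving out 1 library gave 1697 to 3235 (1734 without CON 3, 1822 without CON 4, 1697 without HFD 2, 1730 without HFD 5). ZXD versus HFD gave 0 calls by edgeR (2167 at an unadjusted p under 0.05), 348 by DESeq2, 0 by limma voom, and 1 with the macrophage score as a covariate, Csf1 at -1.15, chosen after its value was seen. Leaving out 1 library gave 0 to 7 (7 without HFD 1, 1 without HFD 3). ZXD versus CON gave 4299 calls, and 6674 with library totals, 384 with the macrophage score, 2184 with the fold minimum and 1888 at an adjusted p under 0.01. Genes with opposite signs numbered 0, against 88 by DESeq2 and 0 to 5 without 1 library (5 without HFD 1). The cause of these differences was not tested. The macrophage score differed between the groups, and the length slope between ZXD and the others, so as covariates they also take out part of the group difference.

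Of 34 lists, camera passed 17 in HFD versus CON, 8 in ZXD versus HFD and 18 in ZXD versus CON. With an estimated correlation it passed 2, 0 and 2. In ZXD versus HFD it passed 14 with the length slope as a covariate, 5 with the length trend removed, 5 with the macrophage score, 0 by fry, and 3 to 13 without 1 library (3 without ZXD 4, 13 without ZXD 2). In the same order of comparisons, fry with a set direction passed 15, 0 and 20 lists. Of these, 14, 0 and 15 were among those that camera passed.

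Some list means changed sign. With the macrophage score as a covariate these were amino acid metabolism (0.15) in HFD versus CON and, in ZXD versus CON, fatty acid oxidation (0.34), xenobiotic metabolism (0.27), inflammatory signalling (-0.19), cell cycle (-0.36) and amino acid metabolism (0.41). Means also changed sign, with camera's direction as before, for bile acid sensing and transport (0.061), circadian clock (0.11) and hepatocyte markers (0.026) in ZXD versus CON and stellate genes (-0.0049) in ZXD versus HFD. The macrophage list became -0.015 in ZXD versus HFD, while in ZXD versus CON its mean stayed above 0 at 0.0094 and only camera's direction turned. Adjusting a list by its own score leaves nothing to test. With the length slope the ribosomal list was 0.028 in ZXD versus HFD.

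Over 164 log2 fold changes of named genes and 26 other settings, 3995 values kept their sign and side of the threshold and 35 changed sign. The low-count filter left 8413 genes untested. Log2 fold changes that changed sign were all of genes that did not pass. In HFD versus CON these were, with library totals, Nr0b2 0.19, Abcb11 0.18, Abca1 0.10, Srebf1 0.39, Scd 0.0055 and Cpt1a 0.11. With the macrophage score they were Nr0b2 0.14, Abcb11 0.26, Srebf1 0.00048 and Cpt1a 0.012. Srebf1 was also 0.13 with the length slope, 0.0021 in the fit of the compared groups, 0.012 by limma voom, 0.27 without CON 1, 0.055 without CON 4 and 0.13 without HFD 3 (lowest -0.18, without CON 2). In ZXD versus HFD, the length slope gave Cyp7a1 -0.013, Cyp8b1 -0.48, Fasn -0.038 and Thrsp -0.23, and the macrophage score Abcg5 0.095, Fasn -0.046 and Cpt1a 0.16. Fasn was -0.082 without ZXD 4, and Sqle 2.4e-05 without HFD 3 (lowest -0.13, without ZXD 2). Cpt1a was 0.0089 by limma voom, 0.02 without HFD 1, 0.12 without HFD 3, 0.0032 without HFD 4 and 0.058 without ZXD 4 (lowest -0.18, without HFD 2). In ZXD versus CON, the macrophage score gave Abcb11 0.17, Abca1 -0.12 and Cpt1a 0.17, the length slope Abca1 -0.11 and library totals Cpt1a 0.068.

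Of the 101 calls of genes under the naming rule in HFD versus CON, 87 held without each library in turn and 14 were lost at least once: Abcg8, Slc27a5, Cd36, Tlr2, Gbp2, Csf3r, Mmp9, Lrat, Slc4a1, Fabp4, Cpb1, Hspa1a, Cdkn1a and Gnmt. Of the 21 in ZXD versus CON, 20 held and Cyp7a1 was lost. Over every setting that tested the gene, also other methods and scales, 52 of the 101 and 10 of the 21 held. The strict filter dropped some of the named genes, and a dropped gene was counted as held. Calls lost numbered 55 with the macrophage score as a covariate, 24 by limma voom, 9 with library totals, 4 with the length slope, 2 with no filter and 1 in the fit of the compared groups.

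With the replicate number as a block, edgeR called 1909, 0 and 3466 genes in HFD versus CON, ZXD versus HFD and ZXD versus CON. Deviations from the group means correlated between libraries of equal number at 0.24, 0.22, 0.26, -0.00057 and -0.08 (numbers 1 to 5) for HFD and CON. For ZXD and HFD they correlated at 0.11, -0.55, -0.05, -0.54 and -0.21. Only HFD 1, HFD 2 and HFD 3 were closest to the library of equal number. This check goes pair by pair and cannot detect numbers that go together across groups. The length slope was positive in CON 1 and CON 4 (0.027 and 0.034) and in HFD 1 and HFD 4 (0.027 and 0.037). It was negative in CON 2, CON 3 and CON 5 (-0.079, -0.048 and -0.053). So it was in HFD 2, HFD 3 and HFD 5 (-0.094, -0.09 and -0.07). In ZXD it was 0.013 to 0.087. The numbers were not taken as pairs, though pairs or another grouping by number are not excluded. With the block 14 calls of genes under the naming rule were lost, those of Abcg8, Tlr2, Gbp5, Gbp2, Lgals3, Cd8a, Csf3r, Mmp9, Fabp4, Cpb1, Hspa1a, Cdkn1a and Gnmt in HFD versus CON and of Abcg5 in ZXD versus CON (edgeR adjusted p from 0.0504 to 0.0948).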

Other observations

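Genes outside the lists set libraries apart within groups; they were chosen after their values were seen, and no test was run. Ugt2b, a glucuronosyltransferase, was 772, 911, 1.14, 805 and 950 CPM in CON 1 to 5, 568, 751, 1.18, 0.886 and 0.678 CPM in HFD 1 to 5, and 519, 575, 1.05, 0.488 and 371 CPM in ZXD 1 to 5. RT1-CE16, a class I histocompatibility gene, was 127, 118, 94.7, 113 and 204 CPM in CON, 122, 214, 1.33, 1.57 and 175 CPM in HFD, and 1.93, 1.09, 1.47, 4.09 and 17.2 CPM in ZXD, each in the order of the replicate numbers.

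Genes of activated macrophages varied widely within the HFD and ZXD groups. Irg1, which makes itaconate, was 7.64, 0.312, 511, 477 and 58.4 CPM in ZXD 1 to 5 and 28.9, 106, 26.2, 0.136 and 59.3 CPM in HFD 1 to 5. Nos2, the inducible nitric oxide synthase, was 0.757, 0.078, 172, 213 and 19.1 CPM in ZXD 1 to 5 and 25.3, 12.5, 2.22, 0.273 and 12.3 CPM in HFD 1 to 5. In CON, the fasting-responsive gene Angptl4 was 68.8, 358, 381, 84.7 and 341 CPM, and the immediate early gene Fos 0.628, 23.2, 13, 0.355 and 6.64 CPM, in the order of the replicate numbers. In HFD, Angptl4 was 5.96, 68.3, 132, 33.1 and 92.4 CPM, again lowest in numbers 1 and 4. Fos was 2.53, 14.4, 3.4, 7.91 and 16.7 CPM in HFD, lowest in numbers 1 and 3.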
